A study of Mus musculus with 2 samples.

How the data were processed

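DNase-seq, which maps chromatin open to cutting by the nuclease DNase I, was measured in 2 libraries of mouse hippocampus. Per the labels, both came from B6CASTF1/J females aged 14 days, a first-generation hybrid of the C57BL/6J and CAST/EiJ strains, and each label names 3 females. The labels number the libraries as biological replicates 1 and 2 of 1 group, under different biosample identifiers and the same donor identifier. Whether the libraries came from separate animals or from separate pools is not given in the sources used here, so the spread between them may be partly technical. With 1 group there was no comparison between conditions. Each measure was described in both libraries, and a call was made only where both libraries passed the same test in the same direction.

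Per the file listings deposited with each library, the authors derived every file from that library's own filtered alignment, on the mm10 assembly, so peaks were called per library and not on pooled reads. The aligner, the peak caller, the footprint caller and their versions are not given in the sources used here. The deposited FDR (q-value) files give the false discovery rate of the cut rate for runs of bases and list only runs with an FDR under 0.05. Each library has 2 deposited peak lists with a signal value per peak, and the authors' columns for score, p and q in these lists hold placeholders. From the values, the lists differ in stringency: 98.7% and 98.6% of the stricter list's peaks in replicates 1 and 2 overlapped the looser list. The looser list was used throughout, as fixed before the data were examined. The deposited footprint files carry a score of 0.01 in every row, so footprints could not be ranked.

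The authors' signal values were whole multiples, within 0.05 of a step, of 0.0076 in replicate 1 and 0.00577 in replicate 2 for 100% of peaks. The scaling is not stated, so no depth in reads is claimed. Signal was therefore used to describe and rank peaks within a library, and ratios between libraries were compared only between classes of peaks. The lists contained peaks that overlap each other, 2234 in replicate 1 and 2183 in replicate 2, and covered length was computed on their union.

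Chromosomes 1 to 19, X and Y of the GRCm38.p6 genome were used, the assembly that mm10 names, with GENCODE M21 gene models. No interval of the FDR files ran past a chromosome end. Coordinates are 1-based on mm10. Peaks were shared when they overlapped by at least 1 bp, beside 100 circular shifts of the other library's peaks within chromosomes. Each peak was assigned to a promoter (within 500 bp of any annotated transcript start), else an exon, else an intron, else intergenic sequence. The smallest two-sided p that 100 shifts can give is 0.0198. The profile around starts used 54052 distinct starts of protein-coding transcripts in 100-bp steps to 2 kb on either side.

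Gene lists were tested on 21701 protein-coding genes with a unique symbol. The 17 lists, with 304 entries that all matched, were markers of cell types the hippocampus can hold (excitatory, inhibitory and pan-neuronal genes, neurogenic progenitors, immediate early genes, astrocytes, oligodendrocyte lineage, microglia, vessels, and ependyma with choroid plexus) and contrast lists (other brain regions, housekeeping, liver, striated muscle, blood lineages, epithelia, germline). The promoter measure was the share of a list's genes with a peak within 500 bp of a protein-coding transcript start. Such a peak can also lie at the start of a neighbouring gene, and it then counts for both genes. Random lists for it were matched on the decile of promoter CpG observed over expected. Promoter CpG and GC were measured within 500 bp of the gene's annotated 5′ end only. The number of transcript starts was not matched, so a peak can lie at a start whose CpG content was not matched. The distal measure was the number of peaks in the gene body and 20 kb either side that lay over 1 kb from every transcript start. Random lists for it were matched on the decile of gene length. Each list was set against 10000 random lists of its size. The two-sided p was adjusted by Benjamini-Hochberg over the 34 tests of a measure. The smallest unadjusted p these lists can give is 0.0002. Genes and peaks are not independent replicates, so every p describes these libraries. The tests are per list, so no gene has an adjusted p of its own.

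Footprints that overlap a peak were extended by 5 bp on each side and searched on both strands for 24 consensus sequences. Windows of the same length 100 bp away on both sides served as the background. Fisher's exact test was adjusted over 48 tests. The standard error of a log2 ratio covers counting error only.

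Named genes followed a rule fixed before the data were examined. From each list these were the 3 members with the most distal peaks (mean of both libraries) and, for contrast lists, up to 3 members with a promoter peak in both libraries, strongest first. Genome-wide, they were the 10 genes with the most distal peaks in the library with fewer, the 10 with the strongest promoter peak by the smaller percentile, and the 5 strongest peaks of each library that the other lacked. Other genes named were chosen after their values were seen. Some genes that the rule covers and some of the consensus sequences are not used here.

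Simulated data were used to test the code. Of 20 lists of 18 genes whose distal counts were raised 2-fold, 20 were called. Of 20 lists whose promoter shares were raised by up to 50 points, 20 were called, and with up to 30 points 3 were called. The raised chance of a peak was capped at its maximum, so genes in the CpG-richest deciles rose by less. No null list was called, 0 of 20 in each simulation. The bar for promoters was first set at 30 points and was moved to 50 after that result, so promoter differences of about 30 points can be missed. The overlap and consensus code returned 60% shared sites for 60% simulated and 5.01% for 5% planted.

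Alternatives were the stricter peak list, equal numbers of peaks, other overlap rules, other promoter and locus windows, unmatched random lists, peak density, other footprint extensions and flanks, distal footprints, a stricter FDR, and leaving out each library. Chosen after seeing the data were a peak within 500 bp as the rule for sharing, footprints wider than the median, and flanks inside peaks. Ranking footprints by score was planned and was not possible. All files were used except the deposited file listings, which hold no measurements. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.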

Results

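Open chromatin in the hippocampus of 14-day-old female mice was mapped in 2 DNase-seq libraries, replicates 1 and 2 of a single group. The deposited looser peak lists held 115699 peaks in replicate 1 and 167829 in replicate 2, which covered 23.7 and 33.8 Mb, or 0.869% and 1.24% of the genome. The median peak was 200 bp wide in both. Median signal was 0.821 in replicate 1 and 0.485 in replicate 2, in units whose scaling is not stated. The depth in reads is therefore unknown.

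By the smaller percentile of both libraries, the promoter of Hjurp, a histone chaperone of centromeres (chromosome 1, 88262471 to 88277633, mm10), ranked first, with a signal of 43.6 in replicate 1 and 23.3 in replicate 2. Bahcc1 followed with 33.4 and 14.1. Acin1 and 1700123O20Rik, which share a promoter peak on chromosome 14, had 30.3 and 13.8. The splicing genes Snrnp70 (29.7 and 12.5) and Hnrnpc (28.8 and 12.7), the methyltransferase gene Prmt5 (28.9 and 12), the ribosomal protein gene Rplp0 (28.7 and 11.6), the chromatin remodeller Chd2 (28.1 and 12.6) and Ankhd1 (27.6 and 13.8) completed the 10.

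Strong sites were found in both libraries and weak sites mostly in a single library. Of the peaks of replicate 1, 70.9% (82085) overlapped a peak of replicate 2. Of the peaks of replicate 2, 49.4% (82921) overlapped a peak of replicate 1. Shifted peaks gave 2.60% and 1.78%. The shared percentage was 23.5% in the weakest signal decile of replicate 1 and 99.4% in the strongest, and 10.7% and 97.0% in replicate 2. Across the 82085 shared peaks of replicate 1, which are not independent replicates, signal correlated with Pearson's r of 0.845 on log2 values and Spearman's rho of 0.792. The signal in replicate 1 was a median of 2.32-fold that in replicate 2 at shared promoter peaks and 1.40-fold elsewhere. The shares depend on the number of peaks: with equal numbers they were 63.1% and 63.3%.

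**Figure D1:**
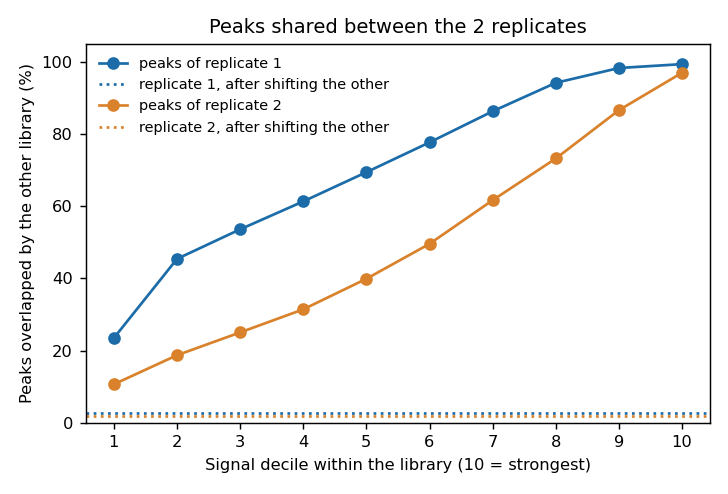
Percentage of each library's peaks overlapped by a peak of the other (vertical axis) by decile of signal within the library (horizontal axis, 10 strongest); lines join points of replicates 1 and 2, and dotted lines give the mean after 100 circular shifts. Sharing reached 99.4% and 97.0% in the strongest decile and was 23.5% and 10.7% in the weakest.

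The strongest peaks found in a single library lay beside peaks of the other. In replicate 1 these were at the promoters of Hnrnpl (chromosome 7, 28810761 to 28810980, signal 18), Rpl27a (16.9), G3bp1 (14.3) and Gatad2b (13.6), and at Zbtb20 (chromosome 16, 42875661 to 42875900, 17.7). The Zbtb20 peak spanned the annotated 5′ end of the gene, 31864 bp from the nearest start of a protein-coding transcript. In replicate 2 the strongest such peaks were an intronic peak on chromosome X (169998261 to 169998420, signal 13.1) nearest to Gm21887, promoter peaks at Hnrnpl (chromosome 7, 28810461 to 28810740, 8.15), Sars2 (6.96) and Slc35b1 (6.65), and a promoter peak 8785 bp from the nearest protein-coding start of Phf19 (6.54). All 10 lay between 0 and 80 bp from a peak of the other library.

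Promoters were the most enriched class. They held 21.9% ± 5.16 of peaks (SD, n = 2), 25.5% in replicate 1 and 18.2% in replicate 2, which was 6.52- and 4.70-fold the share of shifted peaks. With equal numbers of peaks the shares were 25.5% and 22.7%. Exons held 7.32% ± 1.87, introns 36.6% ± 3.17 and intergenic sequence 34.2% ± 3.86 (SD, n = 2). Promoter and exon shares were above, and intergenic shares below, the shifted shares in both libraries, each with the smallest p that 100 shifts can give, 0.0198. Introns were below in replicate 1 (34.3% against 39.0%) and close to the shifted share in replicate 2 (38.8% against 38.9%, permutation p = 0.812). Promoter peaks carried 54.6% of the summed signal in replicate 1 and 38.0% in replicate 2. Of the peaks that the other library lacked, 18.9% were promoters in replicate 1 and 8.29% in replicate 2.

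**Figure D2:**
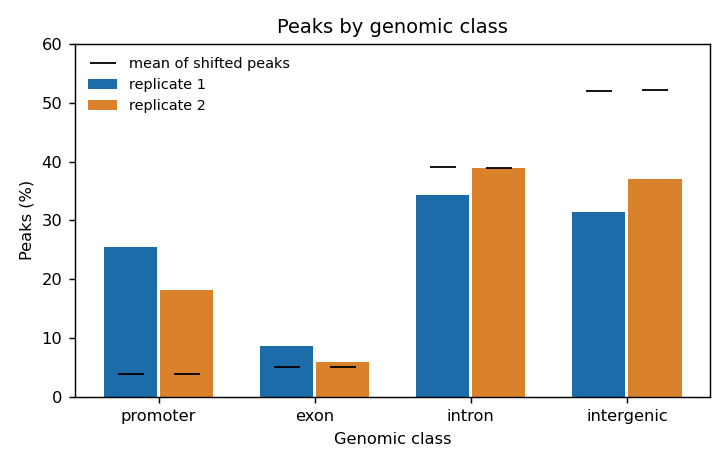
Percentage of peaks (vertical axis) in promoters, exons, introns and intergenic sequence for replicates 1 and 2 (bars), with the mean of 100 circular shifts (black marks). Promoters held 25.5% and 18.2% of peaks against shifted shares of 3.91% and 3.88%.

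Bases at an FDR under 0.05 peaked at transcript starts. In the 100 bp upstream of 54052 protein-coding starts, 53.8% ± 2.19 of bases passed, against 4.04% ± 0.104 at 1900 to 2000 bp upstream and 3.78% ± 0.0432 at 1900 to 2000 bp downstream (SD, n = 2). From 200 to 300 bp downstream the libraries stood apart, with 49.5% in replicate 1 and 41.3% in replicate 2. Genome-wide, 38.6 and 51.9 Mb passed.

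**Figure D3:**
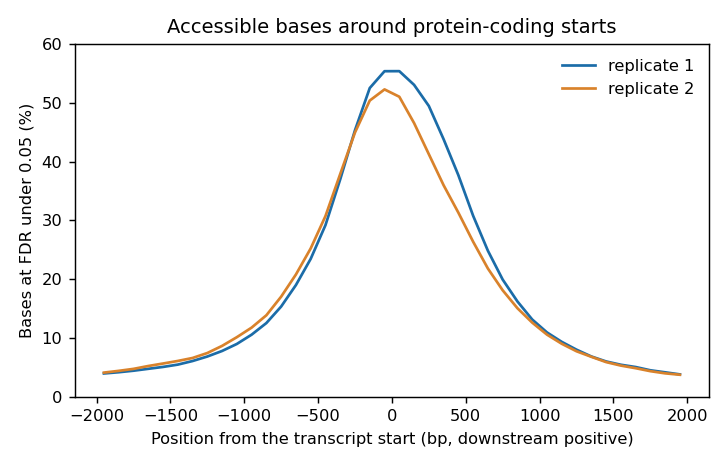
Percentage of bases at an FDR under 0.05 (vertical axis) in 100-bp steps around protein-coding transcript starts (horizontal axis, bp, downstream positive), a line per library. In the first 100 bp upstream the lines reach 55.4% in replicate 1 and 52.3% in replicate 2.

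Excitatory neuron, pan-neuronal, astrocyte and microglial genes had open promoters more often than random genes of the same CpG content at the gene's 5′ end. All 20 pan-neuronal and synaptic genes and all 16 astrocyte genes had a promoter peak in both libraries, against 72.6% and 60.8% in random lists. Excitatory hippocampal neuron genes had one in 95% ± 7.07 (SD, n = 2; random 71.8%), and the exceptions in replicate 2 were Slc17a7, the vesicular glutamate transporter, and Tyro3, both chosen after their values were seen. Microglial genes had one in 75% ± 8.84 (SD, n = 2; random 36.6%). The largest adjusted p of both libraries was 0.00185 for pan-neuronal genes, 0.00136 for astrocyte genes, 0.0453 for excitatory neuron genes and 0.0209 for microglial genes. With the stricter peak list the permutation test no longer called microglial (adjusted p = 1; 31.2% of genes in both libraries, no excess over a random median of 31.2%), excitatory neuron (0.168) or astrocyte genes (0.146). The excess stayed for excitatory neuron genes (95% and 80% against 68.6% and 64.8% in random lists) and astrocyte genes (75% and 87.5% against 56.8% and 53.8%). Over 8 alternatives, which also ended the microglial call without CpG matching and at gene 5′ ends and the excitatory neuron call at 250 bp and at gene 5′ ends, adjusted permutation p ranged from 0.00113 to 1 for microglial, 0.00227 to 0.917 for excitatory neuron and 0.00085 to 0.146 for astrocyte genes.

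Named members show the spread within these lists. Among astrocyte genes, the bicarbonate transporter Slc4a4 had a promoter signal of 1.95 in replicate 1 and 0.606 in replicate 2, the folate enzyme Aldh1l1 had 1.22 and 0.744, and the glutamate transporter Slc1a3 had 1.46 and 0.75. Among microglial genes, the fractalkine receptor Cx3cr1 had 0.745 and 0.519, and Csf1r had 1.43 and 0.704. For excitatory neurons, Camk2a, a calcium-dependent kinase chosen here after its value was seen, had 5.02 and 2.45.

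Germline, liver, striated muscle and other brain region genes had open promoters less often than random genes of the same CpG content at the gene's 5′ end. A promoter peak was present in 8.33% ± 3.93 of germline genes (SD, n = 2; random 52.9%), 2.78% ± 3.93 of liver genes (random 29.6%), 18.4% ± 3.72 of striated muscle genes (random 46.5%) and 34.2% ± 3.72 of genes of other brain regions (random 68.4%). The largest adjusted p of both libraries was 0.00136 for germline and for other brain regions, 0.0453 for liver and 0.0438 for striated muscle. The only germline and striated muscle genes with a promoter peak in both libraries were Dazl, a germ cell RNA-binding protein (5.19 and 1.51), and Mylpf, a muscle myosin light chain (7.27 and 5.31). Whether the promoter peaks of contrast genes lay at the start of a neighbouring gene was not examined. Of the genes of other brain regions, 5 had one in both: Cbln3 (4.56 and 1.62), the serotonin synthesis gene Tph2 (2.49 and 1.01), Pitx3 (1.81 and 0.981), and, chosen after their values were seen, En2 (1.79 and 0.479) and En1 (1.11 and 0.381). No liver gene had one in both, and Apob, chosen after its values were seen, had one in replicate 1. A promoter window of 1000 bp left 1 list lower, with adjusted permutation p of 0.0544 for other brain regions, 0.114 for liver and 1 for striated muscle, the highest of their alternatives except for liver (0.288 at gene 5′ ends). Without replicate 2 the liver list also missed the threshold (adjusted permutation p = 0.051), as it did with a window of 250 bp (0.0609).

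The remaining promoter lists were not called in both libraries. Inhibitory neuron genes differed between libraries, with a promoter peak in 94.4% of 18 genes in replicate 1 and 55.6% in replicate 2. The genes with a peak in replicate 1 alone were Gad2, Slc32a1, Sst, Vip, Dlx1, Reln and Nxph1, all but Reln chosen after their values were seen. The adjusted permutation p for that list was 0.205 in replicate 1 and 0.0349, below random lists, in replicate 2. Epithelial genes had one in 35% and 5%, with an adjusted permutation p of 0.134 in replicate 1 and 0.00136, below random lists, in replicate 2. That list was called lower in both libraries with the stricter peak list (larger adjusted permutation p 0.00247), a window of 250 bp (0.0192), gene 5′ ends (0.0159) and no CpG matching (0.0136). The keratin Krt10 had one in both (6.50 and 2.37). Shares were 97.2% ± 3.93 for neurogenic progenitors (random 86.7%), 70.6% for oligodendrocyte lineage (50.9%), 50% ± 4.16 for vessels (55.9%), 29.2% ± 5.89 for ependyma and choroid plexus (49.4%) and 22.2% for blood lineages (38.6%; SD, n = 2). All 19 immediate early genes and all 19 housekeeping genes had one in both libraries, and random lists of such CpG-rich genes reached 88.2% and 87.5%. These lists were at the 100% maximum, as progenitor genes were in replicate 1, so none could be called higher against these random lists. Blood lineage genes with a promoter peak in both included Pax5 (3.83 and 1.67) and the erythropoietin receptor Epor (2.35 and 1.07). Without CpG matching, progenitor, immediate early and housekeeping genes were called higher and blood lineage genes lower. The larger adjusted permutation p of both libraries ran from 0.108 to 0.873 among the lists not called. In simulated lists of 18 genes, a difference of up to 30 points was called in 3 of 20.

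**Figure D4:**
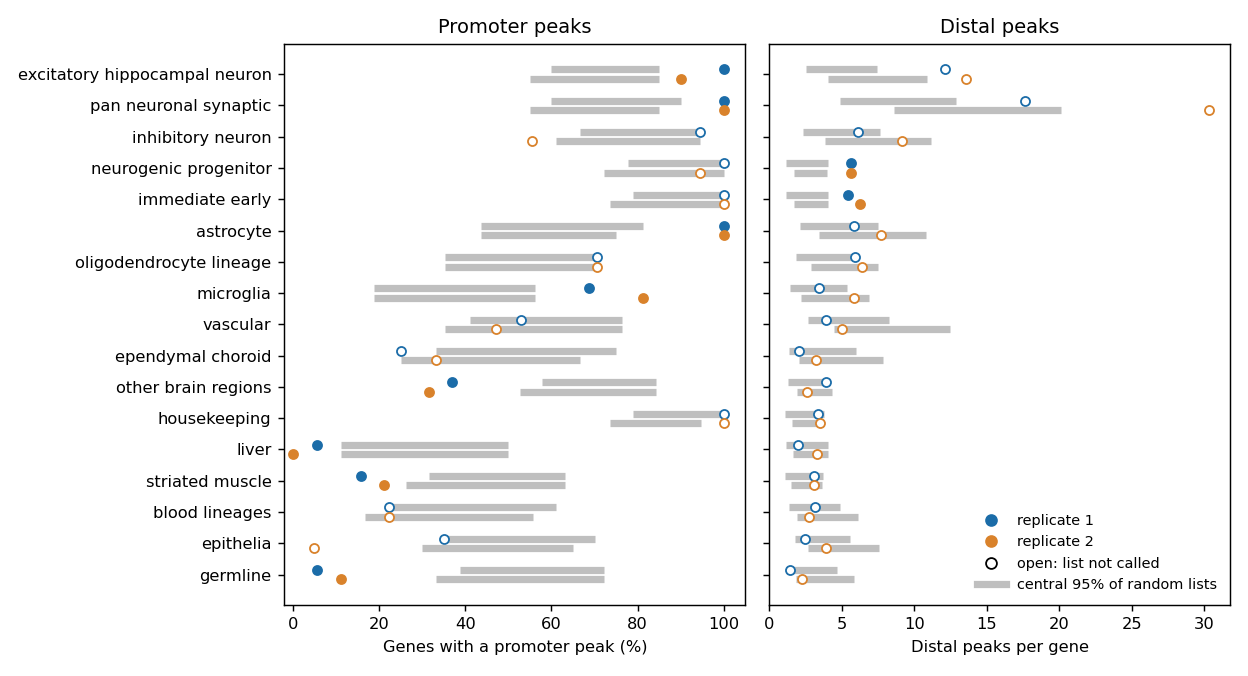
Left, percentage of each list's genes with a promoter peak; right, distal peaks per gene (horizontal axes). Points are replicates 1 and 2, filled where the list was called in both, and grey bars span the central 95% of 10000 matched random lists; 4 lists were called higher and 4 lower for promoters, 2 higher and 0 lower for distal peaks.

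Away from promoters, progenitor and activity-regulated genes carried more peaks than random genes of their length. Neurogenic progenitor genes had 5.67 distal peaks per gene in both libraries, against 2.52 in random lists of the same gene length. Immediate early genes, which neurons induce within minutes of activity, had 5.84 ± 0.595 (SD, n = 2; random 2.55). Both lists had an adjusted p of 0.0238 in replicate 1, and in replicate 2 it was 0.0102 for progenitors and 0.0068 for immediate early genes. Among them, Sox2, a stem cell transcription factor (chromosome 3, 34650405 to 34652461), had 9 and 15 distal peaks in replicates 1 and 2. Sox4 had 8 and 12, Fosb 13 and 11, Btg2 9 and 11, and Fos 9 and 10. Neither list was called in gene bodies alone (adjusted permutation p = 0.120 and 0.173) or without matching on length (0.680 and 0.571, the highest of 8 alternatives), and the 20 kb on either side also holds peaks near neighbouring genes. The progenitor call also ended with the stricter peak list (adjusted permutation p = 0.0552) and with 50 kb on either side (0.0612).

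Excitatory and pan-neuronal genes had the highest counts and passed in 1 library each. Excitatory neuron genes had 12.9 ± 1.03 distal peaks per gene (SD, n = 2; random 5.52), and pan-neuronal genes had 24 ± 8.98 (random 10.7). The adjusted p in replicates 1 and 2 was 0.0449 and 0.0534 for excitatory neuron genes and 0.0722 and 0.0476 for pan-neuronal genes. Grik4, a kainate receptor subunit enriched in CA3, had 78 and 46 distal peaks (chromosome 9, 42518135 to 42944493). The hippocampal transcription factor Zbtb20 had 37 and 74, and Bcl11b had 16 and 19. The splicing factor Rbfox1 had 65 and 127, and the neurexin gene Nrxn3 had 58 and 104. Over 8 alternatives the adjusted permutation p ranged from 0.0017 to 0.120 for excitatory neuron genes and from 0.0340 to 0.498 for pan-neuronal genes. Excitatory neuron genes were called with equal numbers of peaks (adjusted permutation p = 0.0382), with 50 kb on either side (0.0476) and per 10 kb (0.0017), and pan-neuronal genes without matching on length (0.0340).

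No other list was called higher for distal peaks, and none was called lower. Interneuron genes had 7.64 ± 2.16 peaks per gene (random 5.47), astrocyte genes 6.78 ± 1.28 (5.15) and oligodendrocyte lineage genes 6.18 ± 0.333 (4.01; SD, n = 2). Microglial genes had 4.66 ± 1.72 (random 3.40), vascular genes 4.47 ± 0.749 (6.16) and ependymal and choroid plexus genes 2.67 ± 0.825 (3.6; SD, n = 2). The contrast lists had 3.45 ± 0.112 for housekeeping (random 2.39), 3.29 ± 0.930 for other brain regions (2.75), 3.18 ± 1.03 for epithelia (3.88) and 3.08 ± 0.0372 for striated muscle (2.30; SD, n = 2). Blood lineages had 2.94 ± 0.314 (random 3.06), liver 2.64 ± 0.904 (2.54) and germline 1.86 ± 0.589 (2.95; SD, n = 2). Interneuron genes with the most were Erbb4 (16 and 35), Adarb2 (14 and 36) and Reln (16 and 32). The myelin gene Mbp had 28 and 21, Bcas1 8 and 14, and Cspg4, a marker of oligodendrocyte precursors, 13 and 9. Slc4a4 had 16 and 30, Aldh1l1 18 and 17, Slc1a3 11 and 14, Cx3cr1 19 and 29, and Csf1r 7 and 7. In vessels, Erg had 12 and 20, Flt1 14 and 10, and Pecam1 11 and 12. In ependyma and choroid plexus, Aqp1 had 9 and 4, Clic6 4 and 7, and Prlr 1 and 10.

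Contrast genes also had distal peaks. Among genes of other brain regions, Agrp had 19 and 5 distal peaks, Tph2 9 and 9, and Hoxa5 7 and 2. The annotated locus of Agrp spans 105566698 to 105637393 on chromosome 8 and contains another gene. In liver, Hnf4a had 4 and 6 and Cyp2e1 5 and 4. In muscle, Tnni2 had 13 and 4, Myog 7 and 6 and Acta1 5 and 6. Pax5 had 15 and 13, Cd4 12 and 8 and Lck 4 and 5. Vil1 had 11 and 9, Trp63 2 and 15 and Grhl2 3 and 9. Zp2 had 4 and 7, Odf1 4 and 5 and Nobox 3 and 4. Among housekeeping genes, Eef2 had 8 and 5 and Ppia 5 and 6. Strong promoter peaks in that list were at Rplp0 (28.7 and 11.6), Hsp90ab1 (19.9 and 7.41) and Eef2 (20.9 and 6.99).

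Genome-wide, the most distal peaks lay at long loci. In replicates 1 and 2, Auts2 had 74 and 103, the ion channel gene Asic2 69 and 102, Rbfox1 65 and 127, Camta1 63 and 99, the cell adhesion gene Lsamp 62 and 137, Gse1 73 and 59 and Zfhx3 59 and 61. Gm20388 (372 and 377) and Fgfr2 (192 and 245) ranked higher through gene models that run from 119910841 to 124345722 on chromosome 8 and from 130162451 to 133123350 on chromosome 7. Such models span other genes. Counts grow with locus length, and this ranking is not corrected for it.

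Chromosome X was sparse and Y nearly empty. Autosomes had 45.7 and 66.2 peaks per Mb in replicates 1 and 2, and X had 17.6 and 27.8. The X over autosome ratio was 0.402 ± 0.0251 (SD, n = 2), and the autosome with the fewest peaks had 34.8 and 58.0 per Mb. Y held 32 and 33 peaks, 0.349 and 0.360 per Mb, or 0.762% and 0.543% of the autosomal density. The animals are labelled female.

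Footprints, short protected stretches within accessible sites, numbered 316302 in replicate 1 and 366915 in replicate 2, with median widths of 10 and 9 bp. Of these, 84.6% and 90.9% lay in the same library's peaks. Footprints overlapped one of the other library in 41.3% of cases in replicate 1 and 36% in replicate 2, against 17.4% and 14.9% when moved by 100 bp. Among footprints within both libraries' peaks, 54.8% and 58.8% overlapped.

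Sites for CTCF, NFI, RFX, NeuroD-type and several promoter factors were concentrated in footprints. The CTCF consensus CCASYAGRKGGC lay in 1.62% ± 0.0197 of footprints and 0.0590% ± 0.0289 of flanking windows, a log2 ratio of 4.87 ± 0.76 (SD, n = 2). NFI sites, bound by factors of glia and neurons, had a log2 ratio of 4.78 ± 0.15 (SD, n = 2) from 74 and 89 footprints. The larger counting SE of both libraries was 0.67 for NFI and 0.092 for CTCF. Few flanking windows (0.00099%) held an NFI site, so the SD understates the uncertainty of the NFI ratio. RFX sites had a log2 ratio of 2.87 ± 0.55 (SD, n = 2). The E-box RCAGATGG, bound by NeuroD-type factors of excitatory neurons, lay in 1.16% of footprints in replicate 1 and 1.92% in replicate 2, with a log2 ratio of 2.21 ± 0.46 (SD, n = 2). Among activity-regulated factors, CREB sites had 1.98 ± 0.14 and EGR sites 1.96 ± 0.14. General promoter factors had 2.48 ± 0.04 for NRF1, 1.54 ± 0.0022 for SP and KLF, 1.35 ± 0.07 for YY1, 0.84 ± 0.15 for ETS and 0.46 ± 0.05 for NFY (SD, n = 2). Of 24 consensus sequences, 13 were enriched in both libraries by Fisher's exact test. The largest adjusted p among them was 1.78e-11, for YY1. Among these was the E-box CAGCTGTC, included as a muscle control (0.89 ± 0.24).

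Depleted in footprints were 3 sequences, GATA sites with a log2 ratio of −1.55 ± 0.06, the homeobox core TAATTA with −0.86 ± 0.41, and SOX sites with −0.54 ± 0.01 (SD, n = 2). Footprint windows had 62.1% and 55.3% GC and flanks 55.9% and 50.4%, and the test does not adjust for composition. AP1 sites were below the flanks in replicate 1 (log2 ratio −0.21, SE 0.07) and above in replicate 2 (0.13, SE 0.05). MEF2 (−0.33 ± 0.34), REST (0.54 ± 0.28), RORA (−0.71 ± 0.46), PU1 (0.13 ± 0.18) and HNF4 (−0.068 ± 0.19) were not called (SD, n = 2). In distal footprints alone, NFY (log2 ratio 0.26) and ETS (0.55) were no longer called. In footprints within 1 kb of a transcript start, the E-box CAGCTGTC (−0.10) was no longer called and AP1 sites were depleted (−0.40).

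**Figure D5:**
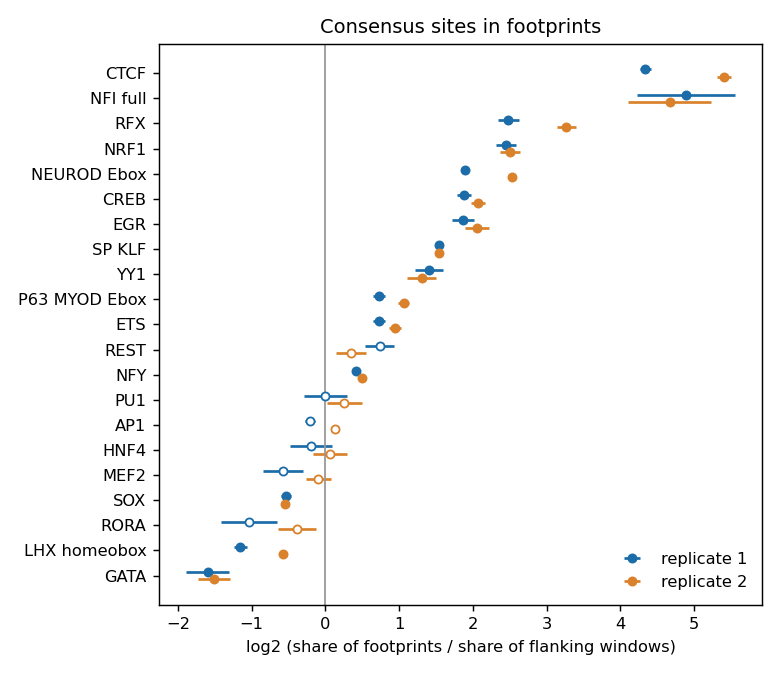
The log2 ratio of the share of footprints to the share of flanking windows with each consensus shown (horizontal axis) in replicates 1 and 2; bars are counting SE, and filled points mark sequences called in both. CTCF had 4.34 and 5.41, and GATA −1.59 and −1.51.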

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

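Settings chosen before the data were examined gave 104 values of the main results. Of these, 76 stayed within 1 SD of the libraries, the binomial interval of a share, or 1.5 times a count. For the other 28, given below, the cause was not tested. The rules for the 104 values do not record a reversal. With n = 2, leaving out a library always moves a mean by less than 1 SD. For measures judged by the SD, those values therefore say nothing about stability. With the stricter peak list there were 83637.5 peaks per library over 17.0 Mb, sharing was 76.1% and 49.9%, Spearman's rho 0.802, promoters 29.3% and introns 32.8% of peaks, the X over autosome ratio 0.372 and Y 0.120 peaks per Mb, with 1 list higher for promoters and 1 for distal peaks. Sharing of replicates 1 and 2 was 63.1% and 63.3% with equal numbers of peaks, 63.1% and 42.1% when at least 0.5 of the peak had to overlap, and 57.6% and 39.7% with midpoints within 75 bp. A promoter window of 1000 bp gave 27.3% of peaks and 1 list lower, and gene 5′ ends alone 2 lists higher. Distal calls numbered 0 in gene bodies only and 1 without matching on length. Leaving out each library gave 3 to 4 higher lists for distal peaks and 3 to 6 depleted sequences, and unextended footprints gave 5 depleted sequences. With a library left out, a call needed only the other library, which by itself allows more calls. Within 100 bp upstream of starts 48.7% of bases passed an FDR of 0.001, with 2.53% and 1.96% at the far upstream and downstream ends. Chosen after seeing the data were a peak within 500 bp (79.6% and 58.3% shared) and footprints wider than the median (156026 per library, 46.4% shared, 5 depleted sequences), and flanks inside peaks, which ended the NFY call (log2 ratio 0.11). Among single lists, 13 of 136 promoter and 6 of 136 distal alternative values lost a call, and 10 and 7 gained one. Ranking footprints by score was not run because the score is constant, and sharing has no value without a library. Depth in reads is unknown, so its limits were not measured. No paired analysis was possible because there is 1 group.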

Other observations

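Every pattern weighed here was noticed in the data first, and the tests of interneuron and epithelial promoter loss were chosen only after the shares per library that they measure had been seen. Promoters on X were weaker and less often open than autosomal ones. Of 948 X genes, 52.0% had a promoter peak in replicate 1 and 48.7% in replicate 2. Autosomal genes with the same CpG content at the gene's 5′ end had 58.7% and 55.9%. Within CpG deciles, the median X promoter signal was 0.569 of the autosomal one in replicate 1 (95% bootstrap interval 0.514 to 0.634) and 0.644 in replicate 2 (0.555 to 0.702). Genes known to escape X inactivation had strong promoters among those on X, between the percentiles 88.7 and 100. Kdm6a had a signal of 24.7 and 12.1, Kdm5c 12.1 and 7.22, Utp14a 10.4 and 5.32, Ddx3x 10.5 and 4.36, and Eif2s3x 7.51 and 3.37.

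The X over autosome ratio of peak density, 0.402, was weighed against gene content and silencing. Fewer genes on X are argued against as the whole source: after division by the ratio of genes per Mb, 0.658, the ratio was 0.584 and 0.637, below the bound of 0.8 set in advance. The lower share of open promoters, 52.0% in replicate 1, lay under the 95% range of matched sets (56.3% to 61.1%), as did 48.7% in replicate 2 (53.4% to 58.3%), and may account for part of it. A silenced X copy in each cell is a candidate explanation for the signal ratios of 0.569 and 0.644, both within the range of 0.4 to 0.7 set in advance. The bootstrap interval of replicate 2 reached 0.702. Silencing is also a candidate for the mean percentile of 97.6 and 96.6 of the 5 escape genes among X promoters. The upper limit was 75.1 in random sets of X promoters with a peak. Those sets were not matched on CpG content, so a high rank through CpG content cannot be told apart from escape. Silencing stays a hypothesis, since the escape genes are also broadly expressed, no allele information was used and the libraries include no males. X and autosomal promoters were also not matched on GC content or on how uniquely reads of either parental strain align to mm10.

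Across shared peaks, the median log2 ratio of replicate 1 to replicate 2 was higher by 0.73 at promoters than elsewhere. Within deciles of peak GC content the difference was 0.055 (95% bootstrap interval 0.043 to 0.066), and over all shared peaks the ratio ran from −0.14 in the decile with 45.0% GC to 1.57 in that with 72.1%. Compression of strong peaks as the whole source is argued against by 0.42 after matching on signal. Depth as 1 scaling factor per library shifts all ratios alike and cancels in this difference, which was 0.54 among peaks above the median in both libraries, and other effects of depth stay open. A difference in GC bias between the libraries is a candidate explanation for this signal ratio and was not tested for the shares of peaks in promoters; no biological explanation was tested, as both belong to 1 group.

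Interneuron and epithelial promoters were often open in replicate 1 alone. Against lists of the same replicate 1 signal and CpG class, 7 of 17 interneuron promoters were lost, 41.2%, at the upper edge of the random range (5.88% to 41.2%), and 6 of 7 epithelial promoters, 85.7% (0% to 71.4%). Both lists were picked because of this loss, so these values decide nothing, and promoters near the calling limit and a true difference cannot be told apart for either list. Genes with a promoter peak in replicate 1 alone (889) had a median promoter GC 10.4 points above those with one in replicate 2 alone (346), with a 95% bootstrap interval of 9.01 to 11.6. The medians were 57.1% and 46.8%, and 58.5% for genes with one in both. The gap has the direction that the same GC bias would give. Promoters open in replicate 1 alone were, however, not richer in GC than those open in both. No biological explanation was tested.

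Of the peaks on Y, 16 of 32 in replicate 1 and 10 of 33 in replicate 2 lay past 90 Mb, at the end of the chromosome. A peak of the other library overlapped 16 of the Y peaks in replicate 1 and 15 in replicate 2. Over all Y peaks the median signal was 0.456 and 0.144, and the highest was 5.33 and 5.31. The source of the Y peaks was not tested.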
